A study of Mus musculus with 6 samples.

How the data were processed

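Expression was measured on 6 Affymetrix mouse M430v2 arrays, each hybridised with RNA from the sorted splenic Tregs of 1 female NOD mouse. Per the labels' protocols, cells were CD4+ and GFP+ and negative for B220, CD8a and CD11b or CD11c, RNA was taken up in Trizol, and it went through 2 rounds of linear amplification before biotin labelling. A second amplification can strengthen 3′ bias, so 3′ to 5′ ratios of control probe sets are given with the results. The series' design text states that the authors processed the arrays with RMA in GenePattern. RMA corrects the background, normalizes between arrays and summarises each probe set. Its version is not given in the sources used here. The deposited values are RMA intensity values on a linear scale, as their range of 5.47 to 29584.9 shows, so log2 was taken here and no further normalization was applied in the main comparison. RMA makes the distributions of the arrays more alike, though the deposited values still differed in spread. A change common to most transcripts could therefore not be seen.

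The table held 45101 probe sets. The 64 control probe sets were left out of all tests, leaving 45037. Gene symbols came from the platform annotation and were updated through gene identifiers, which matched for 34754 of the 34945 probe sets with 1 symbol. A further 932 probe sets had several symbols and 9160 had none. No gene was named from these, and 0 of these 10092 probe sets passed when tested on their own, with 329 at an unadjusted p under 0.05. Each of 18193 genes was represented by its probe set with the highest mean. Other probe sets disagreed in sign for Ikzf4, Socs2, Prdm16, Ikzf2, Il7r, Satb1, Ier5, Rora, Cdkn1a, Xiap, Pmepa1, Slc2a3, Lss, Ncl and Pdgfra among the genes named by rule. The samples fell into 2 groups of 3 by their labels, and since each array held 1 mouse, p-values measure the spread between mice.

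The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes over all 45037 probe sets), with Benjamini-Hochberg adjustment over the 18193 genes and a threshold of 0.05. Intervals are 95% intervals from the same fit. Gene lists were tested with camera at a preset correlation of 0.01 over 25 lists, again with camera at a correlation estimated per list, and with fry. The camera threshold was passed by 6 lists with the preset correlation and by 0 with the estimated one. Fry gave 0 lists in one direction and 3 in either direction. The lists covered genes higher and lower in Tregs, effector, naive, homing, helper lineage and inhibitory receptor genes, and the cell cycle. They also covered responses to the T cell receptor, IL-2, interferon and TGF-beta, apoptosis, T cell identity, glycolysis, oxidative phosphorylation, cholesterol synthesis, ribosome biogenesis and protein folding. The rest held markers of B, myeloid, NK, erythroid, stromal and thymic cells. Of 655 list entries, 604 were measured under a single symbol. Some genes sit in several lists, such as Ccr7 and Gzma.

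Genes to be named were fixed by rule. Those past the threshold with non-overlapping groups were to be named up to 12 per direction by size, and where fewer than 6 passed, those with the smallest p up to 6. Always named were Rag1, Foxp3, Il2ra, Ctla4, Ikzf2, Nrp1, Cd4 and Cd3e, and from each list up to 4 members with the smallest p. Receptor and antibody genes were taken by the start of their symbols, without Tra2a, Tra2b, Tradd and Ighmbp2, which share the letters but lie outside the receptor loci. The groups, tests, lists, naming rule and most alternatives were set before the data were examined.

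The gene test was checked on data simulated over 18193 genes for 3 against 3 samples, with 200 genes altered in each of 10 runs. It called 16.4% of genes altered 2-fold, 82.6% of those altered 4-fold, 94.4% at 8-fold and 97.6% at 16-fold, with 8.5 false calls per run. The simulated genes varied independently with normal noise, and no simulated sample stood apart, so these shares hold for such data only. In the real data Ms4a1 was 35.1-fold lower in treated samples and was not called (limma adjusted p = 0.871). Alternatives covered the replicate number as a block, age and array run as covariates, a filter on dim probe sets, every probe set on its own, the mean of a gene's probe sets, quantile normalization and median centring. They also covered eBayes with trend and robust, array weights, each sample left out, an adjusted p of 0.1, a fold of at least 1.5, and group means of linear values with a fold of at least 2 and no test. The figures were drawn with matplotlib 3.10.9 in Python 3.11.15.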

Results

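Regulatory T cells (Tregs) were compared between 2 kinds of young female NOD mice, the strain that develops autoimmune diabetes. All mice carried the BDC2.5 transgenic T cell receptor, which recognises a pancreatic islet antigen, and a reporter that marks Foxp3-expressing cells with GFP. In 1 group the mice lacked RAG1, the enzyme needed to rearrange receptor genes, and had been injected intravenously with 37.5 µg of the anti-CD3 antibody KT3 daily for 5 days, starting at an age of 17 days. The other group carried 1 working RAG1 copy and was left untreated. CD4+ GFP+ cells were sorted from the spleen at 28 or 29 days of age. For the treated mice the labels give this as 11 or 12 days after treatment, which by the ages counts from the first injection. Each group held 3 mice with 1 array per mouse. Treatment and RAG1 genotype differed together, so every difference below lies between these 2 Treg populations, called treated and untreated, and cannot be assigned to the antibody alone. Probe set intensities ran from 5.47 to 29584.9 and array medians from 85.3 to 92.4. The number of arrays limits the precision, and values are given on the log2 scale as mean ± SD (n = 3 per group) unless stated.

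The comparison addressed how the Tregs present after anti-CD3 treatment differ in transcript levels from those of untreated BDC2.5 mice. Several genes typical of Tregs were much lower in the treated samples, while Foxp3 itself was not. Ikzf4, which encodes the Foxp3 partner Eos, measured 8.02 ± 0.23 in treated and 10.47 ± 0.16 in untreated Tregs, a 5.44-fold lower level (difference −2.44, 95% interval −2.88 to −2.01). Gpr83, a G protein-coupled receptor abundant in Tregs, was 6.78-fold lower at 7.34 ± 0.31 against 10.10 ± 0.38. Ccr7, the chemokine receptor that leads T cells into lymph nodes, was 4.14-fold lower at 5.99 ± 0.37 against 8.04 ± 0.12. Socs2, a suppressor of cytokine signalling, was 3.05-fold lower at 7.58 ± 0.20 against 9.19 ± 0.26. In each of these genes all 3 treated values lay below all 3 untreated values. They were named for their small p values, so this separation adds no further weight.

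No gene passed the threshold over all 18193 genes tested: limma gave 0 higher and 0 lower genes at an adjusted p of 0.05. At an unadjusted p under 0.05 there were 331 higher and 576 lower genes, where chance alone gives about 910. The smallest adjusted p values were 0.0523 for Ikzf4 and 0.0977 for Gpr83. Ccr7 reached 0.133 and Socs2 0.176. Dmd, the dystrophin gene, differed by −1.94 (adjusted p = 0.133) and Adamts6, a secreted metalloprotease gene, by −1.29 (adjusted p = 0.145). Among genes with higher values in treated Tregs, the smallest p values belonged to Slc37a2 (+1.67, adjusted p = 0.133), Prdm16 (+1.79, adjusted p = 0.170), Zan (+1.17), Miat (+1.12), Muc1 (+1.41) and Il1r1 (+0.86), the last encoding an interleukin-1 receptor. Another probe set of Ikzf4, Socs2 and Prdm16 pointed the other way, for Ikzf4 1 of 3 probe sets at +0.17, and with the mean of the probe sets Ikzf4 differed by −1.23, Socs2 by −0.74, Dmd by −0.60, Prdm16 by +0.94 and Miat by +0.60. The groups did not overlap in 1975 genes, 10.9% of all, where chance gives 10%. Without untreated replicate 3 the counts were 1 higher gene and 31 lower genes, and 15 of these 32 were B cell list or antibody genes. Genes outside that list and locus, among them Cd40, Tnfrsf13c, Fcmr, H2-Ob and Ly6d, were not assigned to a cell type. The 15 are therefore not a count of all genes with B cell signal.

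Of 36 measured genes known to be higher in Tregs than in other T cells, 8 passed when adjusted over the list alone and 0 over all genes. Those lower in treated Tregs were Ikzf4, Gpr83, Socs2, Cd83 (−1.51), the enkephalin precursor gene Penk (−2.04) and Swap70 (−0.87). Those higher were Tnfrsf1b, encoding tumour necrosis factor receptor 2 (+1.12), and the cystatin gene Cst7 (+0.80). Penk, Swap70, Tnfrsf1b and Cst7 were singled out after their values were seen. Foxp3 measured 11.78 ± 0.57 in treated and 10.59 ± 0.58 in untreated Tregs (difference +1.19, interval 0.30 to 2.08, adjusted p = 0.914), with all treated values above all untreated ones. The other core Treg genes had smaller differences: Il2ra by −0.05 (interval −0.79 to 0.69), Ctla4 by +0.46 (interval −0.41 to 1.33), Ikzf2, encoding Helios, by +0.04 (interval −0.36 to 0.43), and Nrp1 by −0.30 (interval −0.76 to 0.17), with 2 further Nrp1 probe sets at −0.97 and −0.98. None of these passed the test, and the direction of Il2ra turned with quantile normalization and that of Ikzf2 with the mean of its probe sets. Of all members 17 had a difference above 0 and 19 below, and camera gave the list a direction of lower (median −0.03, mean −0.30, adjusted p = 0.0114). The adjusted p was 0.837 with an estimated correlation, and it was 0.0790 without treated replicate 1, 0.264 without treated replicate 2 and 0.414 without untreated replicate 3. It was also 0.131 after quantile normalization, 0.0696 without dim probe sets, 0.0626 with array weights and 0.161 with the hybridization controls as a covariate. The rotation test fry gave this list an adjusted p of 9.98e-05 for members differing in either direction, and 0.699 for members differing in one direction. The 13 list members at an unadjusted p under 0.05 comprised 5 higher and 8 lower genes.

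**Figure D1:**
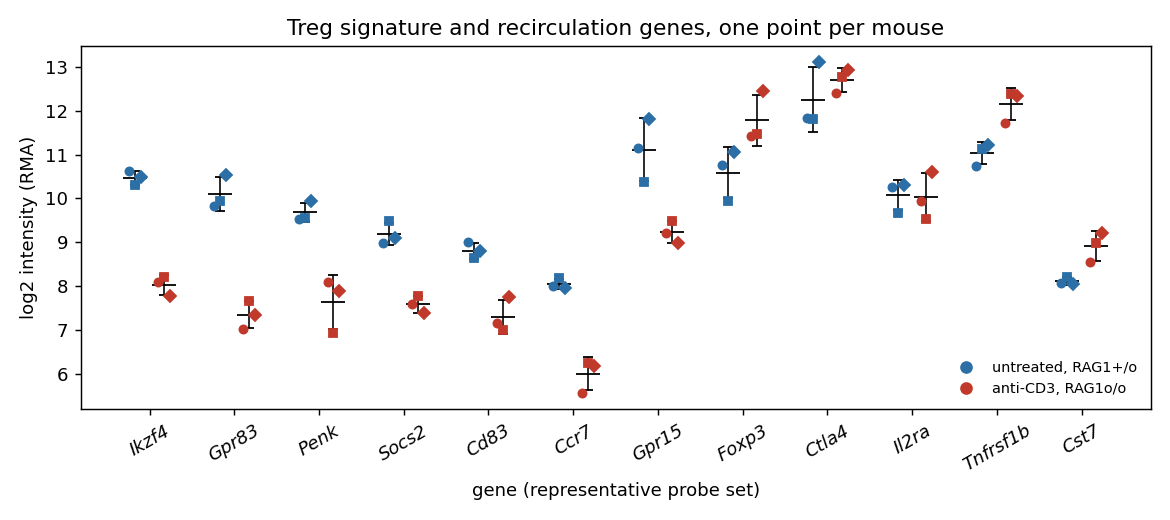
Log2 intensity of 12 Treg signature and recirculation genes in each mouse, untreated in blue and treated in red, with circles, squares and diamonds for replicates 1, 2 and 3 and black bars for mean and SD. Ikzf4 lies near 8.02 in treated and 10.47 in untreated mice, while Foxp3 lies at 11.78 and 10.59.

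Genes of naive and recirculating T cells were lower in treated Tregs as a list. Of 18 measured members, 14 had a difference below 0 and 4 above, with a median of −0.29 (camera adjusted p = 0.00170, and 0.449 with an estimated correlation). Ccr7 alone passed when adjusted over the list alone. Sgk1, a salt-responsive kinase gene, differed by −0.76, the transcription factor gene Foxp1 by −1.0 and the Tec family kinase gene Txk by −0.67, each short of the test. Without untreated replicate 3 the adjusted p of the list was 0.0774, and with array weights 0.0626. Fry in either direction gave an adjusted p of 0.00871, and in one direction 0.612. Among 28 homing and chemokine receptor genes, Ccr7 and Gpr15, a receptor that directs T cells to the colon, passed over the list alone, Gpr15 at 9.23 ± 0.26 against 11.11 ± 0.71. Ccr3 differed by −1.05 and Ccr6 by −0.54. The homing list was not called by camera (adjusted p = 0.0862), but passed it without treated replicate 3 (0.0358), without untreated replicate 1 (0.0353), without untreated replicate 2 (0.00322) and with untreated replicate 3 as the only untreated sample (1.44e-05). Without untreated replicate 3 it was 0.712. Fry in either direction gave an adjusted p of 0.0120, and in one direction 0.821.

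Transcripts of B cells were far lower in the treated samples, and 1 untreated sample lay near the treated ones. All 19 measured B cell markers had a negative difference, with a median of −1.85 (camera adjusted p = 1.15e-16, and 0.449 with an estimated correlation). Adjusted over the list alone, 7 of them passed. Ms4a1, encoding CD20, measured 6.49 ± 0.18 in treated and 11.62 ± 2.29 in untreated samples, and Jchain, the antibody joining chain gene, 5.72 ± 0.11 against 10.99 ± 3.45. Cd79b, a B cell receptor component, differed by −2.84 and the coactivator gene Pou2af1 by −3.01. The mean of the B cell list was 7.28, 7.10 and 7.11 in the treated samples, but 10.13, 10.24 and 7.41 in untreated replicates 1, 2 and 3. In untreated replicate 3, Ms4a1 was at 8.97 and Cd79b at 9.04, above their treated means of 6.49 and 7.65. Of 20 antibody genes, 0 passed over all genes and 0 over the locus alone, and 7 were lower at an unadjusted p under 0.05. Igha differed by −3.31 and Iglv1 by −3.10, and both were named after their values were seen. Without untreated replicate 3, 4 receptor or antibody genes passed over all genes. The sort had excluded cells bearing B220, a B cell surface marker.

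Myeloid and dendritic cell markers had their lowest mean in untreated replicate 3. The mean of the 34 myeloid genes was 10.18, 8.88 and 10.02 in treated replicates 1, 2 and 3, and 9.63, 9.73 and 6.84 in untreated replicates 1, 2 and 3. By camera the list was higher in treated samples, with 32 members above 0 and a median of +0.93 (adjusted p = 7.79e-05). The adjusted p was 0.837 with an estimated correlation and 0.153 without treated replicate 1. Without untreated replicate 3 the direction turned (adjusted p = 0.856). The complement genes C1qa and C1qb differed by +0.53 and +1.24, the endotoxin co-receptor gene Cd14 by +1.04 and Cst3 by +0.60, and none passed over the list alone. Erythroid and platelet markers were not called (median +0.10, adjusted p = 0.842). Ermap differed by +0.65, Hbb-b2 by +0.62, Pf4 by +0.36 and Gata1 by −0.45. Untreated replicate 3 had the lowest mean of this list too, 6.85 against 8.10 to 9.03 on the other arrays. Without this replicate the list was lower in treated samples (adjusted p = 0.00151), and it was higher without untreated replicate 2 (0.0274) and with untreated replicate 3 as the only untreated sample (2.60e-15). The sort had excluded cells bearing CD11b or CD11c, which mark myeloid and dendritic cells.

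**Figure D2:**
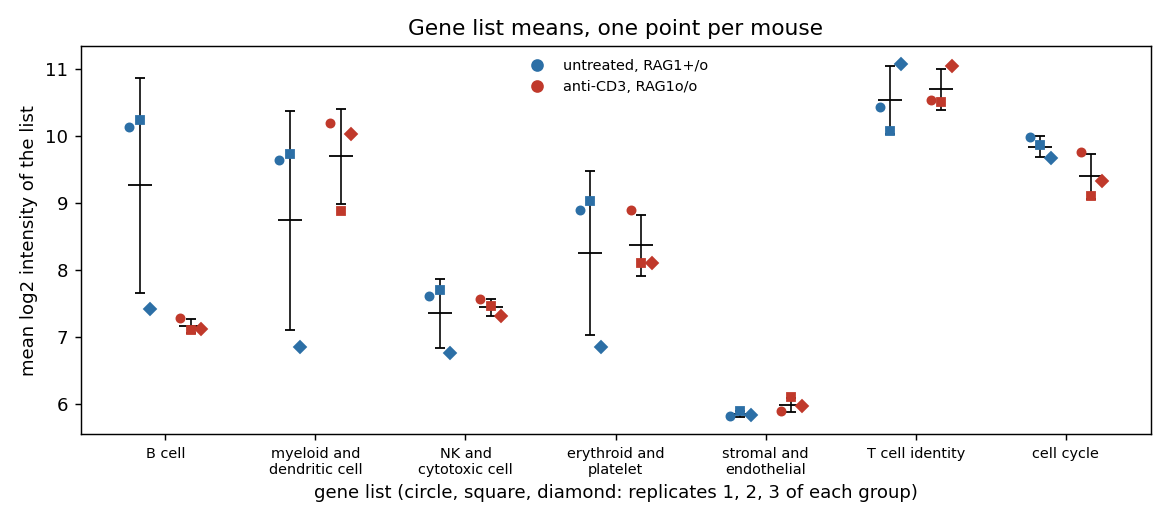
Mean log2 intensity of 7 gene lists in each mouse, untreated in blue and treated in red, with circles, squares and diamonds for replicates 1, 2 and 3 and black bars for mean and SD. Untreated replicate 3, the lowest blue diamond, has the lowest myeloid value of all samples, 6.84, and a B cell value of 7.41 beside 10.13 and 10.24 in the other untreated mice.

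The granzyme genes Gzma and Gzmk passed over the list alone among 24 NK and cytotoxic markers. Gzma was 3.98-fold lower in treated samples, at 9.02 ± 0.37 against 11.02 ± 0.82, and Gzmk 1.79-fold lower. In untreated replicates 1, 2 and 3 Gzma measured 11.46, 11.52 and 10.08. Gzmb differed by −0.78 and Eomes by +1.22, short of the test. As a list these markers were not called (adjusted p = 0.718), with a median of +0.05, a mean of +0.09 and a camera direction of lower. Stromal and endothelial markers were not called either (median +0.13, adjusted p = 0.425), with Sparc at +0.43, Pdgfra at +0.47, Vwf at +0.71 and Madcam1 at +0.33. General T cell genes were not called (19 genes, median +0.27, adjusted p = 0.539). Cd3e measured 12.05 ± 0.10 in treated and 11.74 ± 0.10 in untreated samples, and Cd4 differed by +0.37. Trat1 differed by −1.48, Cd247, the CD3 zeta chain gene, by +1.05 and Zap70 by +0.83. Without untreated replicate 3 the T cell list was higher in treated samples (adjusted p = 0.00967). With untreated replicate 3 as the only untreated sample the T cell list was lower (0.000110) and the NK list turned to higher (0.000658).

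Cell division genes had lower values in treated samples by camera with the preset correlation, a call lost with an estimated one. Of 46 measured members, 38 had a negative difference and the median was −0.45 (camera adjusted p = 4.11e-12, and 0.449 with an estimated correlation), and 10 were lower at an unadjusted p under 0.05. The mitotic kinase genes Aurkb and Cdk1 differed by −1.10 and −0.82, and the spindle genes Hmmr and Nusap1 by −0.77 and −0.72. None passed over the list alone. The list mean gave an exact two-sided permutation p of 0.2. List means were 9.76, 9.10 and 9.32 in treated replicates 1, 2 and 3 and 9.98, 9.87 and 9.66 in the untreated ones, beside the B cell values given above. The 21 unfolded protein and heat shock genes were also lower by camera (median −0.30, adjusted p = 0.0258, and 0.449 with an estimated correlation), with 16 members below 0. Pdia6, an endoplasmic reticulum folding enzyme gene, differed by −0.97, the secretory pathway regulator Xbp1 by −0.44, the chaperonin gene Hspd1 by −0.64 and Ddit3 by +0.42. None passed over the list alone. The call was lost without treated replicate 1 (0.156) or 2 (0.0868), without untreated replicate 1 (0.0761) or 3 (0.0774), after quantile normalization (0.0961), without dim probe sets (0.0696), with untreated replicate 3 alone (0.0584) and with the hybridization controls as a covariate (0.0868). Ribosome biogenesis genes were not called (median −0.21, adjusted p = 0.107), with Fbl at −1.18, Ncl at −0.73, Nop58 at −0.79 and Ppan at +0.52. They passed without treated replicate 3 (0.00273).

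Markers of effector Tregs were not called as a list (31 genes, median +0.14, adjusted p = 0.818). Lgals3 differed by +1.16 and Nfil3 by +0.86, while Gzma differed by −1.99 and Gzmb by −0.78. Genes normally lower in Tregs than in other T cells were not called (median +0.13, adjusted p = 0.913), with Bach2 at −1.59, Il7r at +0.51, Satb1 at −0.38 and Id3 at +0.51. Bach2 measured 9.79, 10.24 and 8.53 in untreated replicates 1, 2 and 3, the order of their B cell list means. Of the early genes induced through the T cell receptor, Nr4a1 passed over the list alone at 10.27 ± 0.10 against 9.46 ± 0.14. The other members went both ways, with Jun at −0.61, Ier5 at −0.37 and Ier3 at +0.62, and the list was not called (median +0.08, mean +0.0003, camera direction lower, adjusted p = 0.818). The inhibitory receptor genes Pdcd1 and Lag3 differed by +1.67 and +0.67, the diacylglycerol kinase gene Dgkz by +0.92 and Btla by −0.84, and their list was not called (median +0.06, adjusted p = 0.661). Btla measured 12.83, 12.92 and 11.80 in untreated replicates 1, 2 and 3, also the order of their B cell list means, against a treated mean of 11.68. Among helper lineage genes Il18r1 differed by +1.00, Stat6 by +0.71, Rora by −0.48 and Ebi3 by −0.55 (median +0.17, adjusted p = 0.240, and 0.0407 without dim probe sets). IL-2 and STAT5 response genes were not called (median +0.07, adjusted p = 0.576), with Socs3 at +0.72, Lif at +0.39 and Xcl1 at +0.31.

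Ifit3 passed over the list alone among 35 interferon response genes, at 8.31 ± 0.17 in treated and 9.24 ± 0.19 in untreated samples. Usp18 differed by −0.84, Rtp4 by −0.53 and Oas1a by −0.45. The interferon list was not called (median −0.06, adjusted p = 0.107), but passed with the mean of the probe sets of each gene (0.0497), without treated replicate 3 (0.00273), without untreated replicate 2 (0.00848) and with untreated replicate 3 as the only untreated sample (0.00701). TGF-beta response genes were not called (median −0.16, adjusted p = 0.363) but passed without treated replicate 3 (0.0380), and Pmepa1 differed by −1.04, Smurf2 by −0.51, Tgfbr2 by −0.45 and Id1 by +0.30. Apoptosis regulators were not called (median +0.05, mean −0.10, camera direction lower, adjusted p = 0.646), with Tnfsf10 at −0.96, Cdkn1a at +0.56, Bak1 at +0.57 and Xiap at −0.43. None of the metabolic lists was called. Glycolysis had a median of +0.18 (adjusted p = 0.477) with Slc16a3 at +0.48 and Slc2a3 at +0.47. Oxidative phosphorylation had a median of +0.19 (adjusted p = 0.818) with Ndufv2 at +0.58 and Ndufs1 at −0.42, and cholesterol synthesis a median of +0.06 (adjusted p = 0.860) with Dhcr7 at +0.82. Without treated replicate 2, glycolysis (0.0145) and cholesterol synthesis (0.0188) passed, and glycolysis also with the hybridization controls as a covariate (0.0359). Oxidative phosphorylation passed as higher without untreated replicate 1 (0.0351) and as lower without untreated replicate 2 (0.00848).

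**Figure D3:**
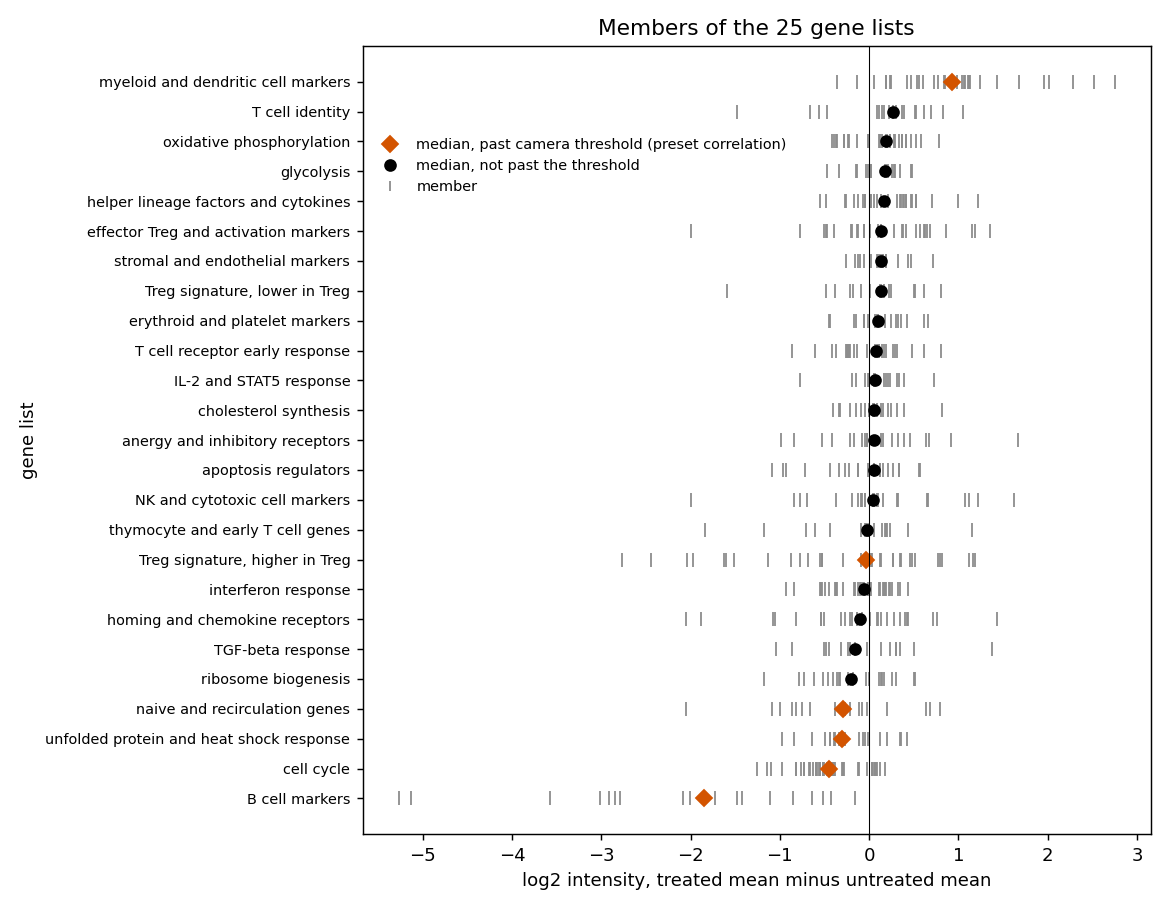
Difference of the log2 means, treated minus untreated, for each measured member (grey ticks) of 25 gene lists, with the list median as an orange diamond where camera with a preset correlation passed the threshold and as a black circle otherwise. B cell markers have the lowest median, −1.85, and myeloid markers the highest, +0.93.

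The RAG1 genotype could not be checked through Rag1 itself on these arrays. The B cell list means were low in the treated samples (7.28, 7.10 and 7.11) but also in untreated replicate 3 (7.41), so they did not settle it. Rag1 has 1 probe set, whose place relative to the deleted part of the gene is not known here. It measured 5.61 ± 0.94 in treated and 6.79 ± 1.16 in untreated samples (difference −1.18, adjusted p = 0.914), and untreated replicate 3 lay at 5.47, within the treated range. Genes of immature thymocytes were not called (median −0.02, adjusted p = 0.461), with Ly6d at −1.84, Themis at −0.70, Cd1d1 at −0.61 and Notch1 at +0.44. Ly6d measured 9.11, 8.67 and 6.67 in untreated replicates 1, 2 and 3, and without untreated replicate 3 it differed by −2.58 (adjusted p = 0.0182). Of 10 measured T cell receptor genes, 0 passed over all genes and 0 over the locus alone. At an unadjusted p under 0.05, Trav13-5 (+0.80) and Trgv1 (+0.76) were higher, and Trgv4 (−0.55) and Trav12n-1 (−0.53) lower in treated samples. These 4 were named after their values were seen.

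Measures of array quality overlapped between the groups. The ratio of 3′ to 5′ signal of actin was 2.33 ± 1.15 in treated and 1.39 ± 0.52 in untreated samples on the log2 scale (exact two-sided permutation p = 0.3), and that of Gapdh 3.71 ± 0.36 against 3.04 ± 0.94 (exact permutation p = 0.4). Untreated replicate 3 had the lowest value of both, 0.922 for actin and 2.02 for Gapdh, where the other arrays had Gapdh values of 3.23 to 4.10. The smallest p that this design allows is 0.1. The log2 values of treated replicate 2 had the smallest SD over probe sets, 2.00 against 2.15 to 2.21 on the other arrays. Array weights, used as an alternative, were lowest for treated replicate 2 at 0.24 and highest for untreated replicate 1 at 2.58. Correlations between arrays over all probe sets lay between 0.949 and 0.989. The highest was between treated replicate 1 and untreated replicate 1, above that of every pair within a group.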

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

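The tests of the 3 patterns below were chosen after the results were seen, except the counts over other splits of the samples for genes and for lists past the threshold. The hybridization control BioB, spiked in before hybridization, read 12.88 on the array of treated replicate 2, above the highest untreated array at 9.56 (log2). The 3′ to 5′ ratio of actin read 3.62 in treated replicate 3, above the highest untreated value of 1.95 (log2).

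B cell markers were lower in the treated samples. Untreated replicates 1 and 2 lay 2.19 above untreated replicate 3 in the median of 19 markers, and 19 of 19 shared this direction, which is consistent with RNA of B-lineage cells in the sorted samples, most in those 2, despite the B220 gate. Untreated replicate 3 lay 0.092 above the treated mean (quartiles −0.017 and 0.44), with 13 of 19 markers above it, among them Ms4a1 at 8.97 against 6.49 and Cd79b at 9.04 against 7.65. Lower expression by the Tregs themselves stays open, since a single untreated sample cannot exclude it. The RAG1 genotype is part of the design, and mice without RAG1 lack B cells.

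Ikzf4, Gpr83, Socs2, Cd83, Penk, Swap70, Ccr7 and Gpr15 were lower in treated Tregs, with a median of −1.96. Cells other than Tregs in the treated sort, if they made up the whole difference, would lower the core Treg genes by about as much. Foxp3, Il2ra, Ctla4, Ikzf2 and Nrp1 had a median difference of 0.036. The lowest lower 95% limit over all their probe sets was −1.59, for a Nrp1 probe set at −0.97. That median depends on untreated replicates 1 and 2, which were high in B cell markers. In untreated replicate 3, Il2ra measured 10.30, Ctla4 13.10, Ikzf2 12.74 and Nrp1 10.70, above their treated means of 10.03, 12.71, 12.55 and 10.48. Foxp3, at 11.07 against 11.78, went the other way. The median of −1.96 is enlarged, however, because its genes were chosen as lower in these same data, and the sort itself selected for the Foxp3 reporter. A smaller contribution of other cells stays open. A technical difference of the array of treated replicate 2, whose BioB control read highest at 12.88, stays open. Over 8 genes chosen on that array against 2 untreated samples, treated replicates 1 and 3 differed from the untreated sample left out by medians between −1.84 and −1.41. The highest upper quartile, however, was 0.079. B-lineage RNA in untreated replicates 1 and 2 stays open too. Over 9 genes chosen on the other 5 samples, untreated replicate 3 lay 1.96 above the same treated mean (quartiles 1.49 and 2.46). The treated samples took part in that choice of genes, so this value can be enlarged too. Untreated replicate 3 is, moreover, a single sample with some B cell signal of its own. The myeloid list mean of untreated replicate 3 was also far lower, 6.84 against 10.18, 8.88 and 10.02 in the treated samples, so this comparison does not isolate B-lineage RNA. A difference of the Tregs themselves is open as well, untested as to antibody or RAG1 genotype, since these differ together.

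Cell cycle genes were lower in treated samples, with a median of −0.45. A technical difference of the array of treated replicate 2 stays open. The median was −0.32 without that array, but the list mean of treated replicate 1, 9.76, lay above that of untreated replicate 3, 9.66. B-lineage RNA in untreated replicates 1 and 2 stays open too: untreated replicate 3 lay 0.28 above the treated mean, with a lower quartile of −0.013. Genes of the list moving together from sample to sample may account for the small preset p, since the adjusted p was 0.449 with an estimated correlation and the exact permutation p of the list mean was 0.2. Treatment and genotype are open as well, as untested.

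The 6 samples can be split into 3 and 3 in 10 ways, too few for a share under 0.05. All 10 gave at least the 0 genes of the real split, which was certain in advance, so this count decided nothing. The highest other split gave 3. That split set treated replicate 1 with untreated replicates 1 and 2, and it had 1840 genes at an unadjusted p under 0.05 beside 907 in the real one. For lists past the camera threshold, 6 splits gave at least the real 6, and the highest other gave 13.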

How the results depend on the processing

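The settings with untreated replicate 3 alone and with the hybridization controls as a covariate were chosen after seeing the data, the others before. The 0 higher and 0 lower genes of limma stood with age, array run, every probe set, mean probe sets, quantile normalization, trend and robust, a fold of 1.5 and the hybridization covariate. Under the replicate block they were also 0 and 0, and 5 lists were called in place of 6, without the list of genes higher in Tregs (adjusted p = 0.0683). Same-numbered samples had correlated deviations of 0.513, 0.010 and 0.103, not every sample matched its own number best, and no label says that a number marks a shared batch, although array numbers in the labels are consecutive within each number, so the numbers were not taken to pair mice. Lower genes numbered 1 without dim probe sets and 1 after median centring (Ikzf4 in both), 2 at an adjusted p of 0.1, and 4 with array weights, which also gave 1 higher gene. Linear group means with a fold of at least 2 and no test gave 86 higher and 206 lower. With untreated replicate 3 alone there were 2 higher genes and 10 lists. Lists called were 0 with an estimated correlation and 0 by fry in one direction. Leaving out each sample gave 0 to 1 higher genes, 0 to 31 lower genes, 0 to 4 receptor and antibody genes and 3 to 10 lists. The extremes of the gene counts came without untreated replicate 3. A left-out sample also leaves fewer degrees of freedom, and apart from that the cause was not tested. The lone untreated sample was assumed to vary like the treated ones.

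Among 111 named genes, 17 of 1991 values under alternatives had the opposite direction, and none of the 17 passed the test. Il2ra reached 0.053 with age, 0.044 with quantile normalization and 0.17 with the hybridization covariate. With the mean of probe sets Ikzf2 was −0.20 and Xiap 0.019. With untreated replicate 3 alone, Rag1 was 0.14, Ctla4 −0.40, Ikzf2 −0.19, Id3 −0.12 and Gata1 0.79. Leaving out samples, Il2ra ran from −0.34 to 0.20, Ikzf2 from −0.045 to 0.15, Ermap from −0.39 to 1.30, Pf4 from −0.085 to 0.71 and Hbb-b2 from −0.45 to 1.27. The cause was not tested.

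Of 375 list values, 38 turned. With untreated replicate 3 alone, adjusted p values of turned lists were 0.128 for effector, 0.672 for IL-2, 0.657 for inhibitory receptor, 0.888 for apoptosis, 0.000110 for T cell identity, 0.418 for oxidative phosphorylation, 0.632 for cholesterol, 0.000658 for NK and 0.534 for thymocyte genes. The early receptor response turned with mean probe sets (0.661), quantile normalization (0.886), array weights (0.772), fry (0.905) and the hybridization covariate (0.820). Mean probe sets also turned genes lower in Tregs (0.533) and oxidative phosphorylation (0.845), and the dim filter stromal genes (0.888). Leaving out samples turned 12 lists at least once, with adjusted p values over the 6 fits of 0.0774 to 0.824 for NK, 0.00967 to 0.806 for T cell identity, 0.440 to 0.945 for early receptor response, 0.0380 to 0.859 for TGF-beta, 0.537 to 0.967 for genes lower in Tregs, 0.0868 to 0.795 for inhibitory receptors, 0.0188 to 0.726 for cholesterol, 0.259 to 0.934 for effector, 0.00151 to 0.759 for erythroid, 0.0145 to 0.603 for glycolysis, 2.14e-12 to 0.856 for myeloid and 0.00848 to 0.806 for oxidative phosphorylation genes. The cause was not tested. Signal near background limits low probe sets such as Rag1.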

Other observations

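All tests in this part were chosen after the results were seen. Neutrophil transcripts were among the brightest signals on 5 of the 6 arrays. Ngp, a granule protein gene of developing neutrophils, measured 14.56, 13.81 and 14.20 in treated replicates 1, 2 and 3, and 14.27, 14.40 and 6.33 in untreated replicates 1, 2 and 3. Chil3, a chitinase-like gene of myeloid cells, measured 14.27, 13.62 and 14.15 in treated and 13.71, 14.43 and 5.37 in untreated samples. S100a8 was likewise lowest in untreated replicate 3, with 14.19, 12.96 and 13.75 in treated and 13.67, 12.19 and 6.80 in untreated samples. These genes were picked after their values were seen.

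Treg signature genes may differ between the populations more often than other genes of like expression. The list held 13 of 36 members at an unadjusted p under 0.05. Of 10000 random lists of the same size matched on mean expression, 0% held as many, and their median was 3 and their highest 10. Genes within a list are not independent, and random lists lack the shared regulation of a real one. Over the 10 splits of the samples, 1 split gave as many as 13, the real one, and the highest other gave 6, and 10 splits are too few for a share under 0.05.

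A shift of treated Tregs from a resting towards an effector state may underlie the lower Ccr7 values. It would raise the effector list, whose camera adjusted p was 0.818 with a median of +0.14, so the test decided nothing. Of the 31 effector list members, 19 had a difference above 0 and 12 below. Members without overlap between the groups went both ways, such as Lgals3, Nfil3 and S100a4 with higher and Gzma, Rora and Cd69 with lower treated values. Gzmb had a lower mean and Klrg1 differed by −0.20.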
